A study of Homo sapiens with 18 samples.

How the data were processed

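RNA sequencing was used to measure gene expression in 18 libraries from 4 human B-cell lymphoma cell lines. They form 6 groups of 3 replicates: SU-DHL16 parental and DTEP cells, Namalwa parental and DTEP cells, EJ-1 parental cells and BJAB cells. DTEP is the submitters' own name for the drug-resistant variants. Per the labels' protocols, total RNA was isolated with the RNeasy Plus kit and libraries were made with a stranded TruSeq mRNA kit, which selects polyadenylated transcripts.

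The authors deposited 1 table of TPM, a length-adjusted share of a library's transcripts, with 27347 gene symbols and a column for each of the 18 libraries. Per the submitters' processing notes, TopHat2, Cuffnorm and the genome build hg38 were used. Their versions, the annotation, the strand setting and the step from Cuffnorm output to TPM are not given in the sources used here. The deposited TPM values of a library sum to between 986241 and 989816. TPM keeps no sequencing depth, so the number of reads behind each value is unknown and no counting interval is given. No 2 libraries held identical values. In the table, 25 gene names had been turned into dates and stayed as they were. A value of exactly 0 is described only as listed at 0.

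TPM is a share of a library, so a few abundant transcripts that rise lower the values of all others. For this reason the median change over all tested genes is given, and other scalings were tried. Multigene families such as the HLA, OAS, IFITM, HSPA1A/HSPA1B, CTAG and MAGE genes share sequence. How reads that match several copies were assigned is not given in the sources used here, so single members of these families are uncertain. The same holds for genes that overlap.

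All tests were run in R 4.3.3 with limma 3.58.1. Values were transformed as log2(TPM + 1), a scale on which the change of genes with low values is understated. Log2 changes and their standard errors (SE) are on this scale. A gene was tested where TPM was at least 1 in at least 3 libraries of the fit. Each comparison was fitted to its own 6 libraries with lmFit and eBayes with trend, and the difference between the DTEP effects of both lines to their 12 libraries. Benjamini-Hochberg adjustment ran over the genes tested. A gene was called at an adjusted p below 0.05 and a change of at least 1 on the log2 scale, and passed the test at an adjusted p below 0.05 alone.

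A set of 37 gene lists with 667 genes, of which 640 are in the table, covered apoptosis, B-cell programmes, antigen presentation, signalling, metabolism, stress, cell cycle, RNA quality and other cell types. Lists with at least 5 tested members were tested with limma's camera against all other genes, at a preset inter-gene correlation of 0.01 and, as an alternative, with an estimated correlation. Members were also counted after adjustment over the list alone. The lists of mitochondrially encoded transcripts and of erythroid markers had 0 tested members in each comparison. Of the 13 mitochondrially encoded transcripts listed, 0 are in the table, whereas all 11 erythroid markers are. The overlap of calls between lines was set against the overlap of independent lists, with Fisher's exact test, 1-sided.

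The genes named in the text follow a rule. For each DTEP comparison these are the 6 called genes with the largest rise and the 6 with the largest fall. They needed a mean of at least 5 TPM in the higher group and replicates that did not overlap. For BJAB against EJ-1, 5 in each direction were taken. All BCL2 family members, up to 4 members of each described list with the smallest adjusted p, and up to 5 genes called in both lines in each direction were added. Genes on the Y chromosome, XIST, immunoglobulin and T-cell receptor segments, pseudogenes, unnamed loci and read-through names were left out of the ranked parts. Groups, the tests of the comparisons, gene lists, the rule and all alternatives except 1 were fixed before the data were examined. Some tests of explanations were chosen later. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

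Coordinates come from GENCODE release 29 on GRCh38, the assembly that hg38 names, matched by symbol in Python 3.11.15 with pandas 2.3.3. Of the 27347 symbols, 25134 (91.9%) matched. Figures were drawn with matplotlib 3.10.9.

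The scripts were tested on simulated data in which 200 genes were changed. These were drawn only from genes of higher mean expression and shifted directly on the log2 scale, so recovery at low TPM was not simulated. In the SU-DHL16 simulation of 11057 genes, 100% of the genes changed by 1.5 on the log2 scale were recovered, and in the Namalwa simulation of 12294 genes 97%. For the difference between lines it was 98% of those genes, with 4 unchanged genes called among 12447. For BJAB against EJ-1 it was 99%, with 2 unchanged genes called among 12286. In each simulation 100% of the genes changed by 3 were recovered, and the shifted gene list was called with 0 other lists. Genes were drawn independently there, so this does not test how many lists camera calls among correlated genes. In the real libraries, splits that mixed the groups called up to 14 lists in SU-DHL16, 10 in Namalwa and 10 for BJAB against EJ-1.

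Alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, quantile normalization, upper-quartile scaling, and rescaling without immunoglobulin, mitochondrially encoded and ribosomal protein genes. The listed mitochondrially encoded transcripts are absent from the table, so the rescaling had none of them to remove. A fit of all 18 libraries, a replicate block, calls by adjusted p alone, eBayes without trend or with robust estimation, and leaving out each replicate were also run. With a replicate left out, the filter still asked for 1 TPM in at least 3 libraries. In each single comparison, a gene below 1 TPM in every library of the intact group was then not tested. Counts with a replicate left out therefore reflect the filter as well as the spread. After the data had been seen, a fit without a pair of Namalwa libraries that stand apart was added.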

Results

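S63845 is a small-molecule inhibitor of MCL1, a BCL2 family protein that keeps cells from apoptosis. SU-DHL16, a diffuse large B-cell lymphoma line, and Namalwa, a Burkitt lymphoma line, had been kept in 2 uM of the drug for about 6 months. The resulting DTEP variants spent 1 week in drug-free medium before use, and parental cells exposed to DMSO ran in parallel. EJ-1 is labelled as drug-naive. BJAB is labelled as parental, resistant and drug-treated, although the growth protocol names only Namalwa and SU-DHL16 as treated. All 18 libraries carry mantle cell lymphoma as their source, which is not the usual description of SU-DHL16, Namalwa or BJAB.

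Each of the 6 groups holds 3 libraries, and between 11030 and 12586 genes reached 1 TPM in a library. Sequencing depth is unknown. Nothing in the labels says that the replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical. With 3 libraries against 3, an exact permutation test of a lone gene could not go below a 2-sided p of 0.1, and chance alone would leave 10% of genes without overlap between groups. Values are mean TPM ± SD with n = 3 unless stated, and log2 changes are given ± SE.

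The BCL2 family was followed in every group, since S63845 binds one of its members. BCL2, an anti-apoptotic relative of MCL1 (chromosome 18, 63123346 to 63320128, minus strand), rose in DTEP cells of both lines. It went from 51.8 ± 0.866 to 109 ± 5.79 TPM in SU-DHL16 and from 31.7 ± 5.72 to 70.2 ± 6.88 TPM in Namalwa. The changes were 1.06 ± 0.046 and 1.13 ± 0.13 (limma with Benjamini-Hochberg adjustment, adjusted p = 5.48e-07 and 0.00114). They differed by 0.07 ± 0.15 between the lines, with adjusted p = 0.745 in limma's test of the difference, Benjamini-Hochberg adjusted, and by -0.09 and -0.06 with upper-quartile and rescaled values. Namalwa parental replicate 2 read 38.3 TPM of BCL2, against 28.5 and 28.3 in replicates 1 and 3. The sizes of the Namalwa change and of the difference thus depend in part on that library.

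MCL1 (chromosome 1, 150574551 to 150579738, minus strand) stood at 147 ± 2.24 and 142 ± 4.43 TPM in SU-DHL16 parental and DTEP cells. In Namalwa it stood at 129 ± 3.82 and 141 ± 16.8 TPM. Neither comparison passed the test, with limma adjusted p = 0.349 and 0.355 after Benjamini-Hochberg adjustment, and the SU-DHL16 change of -0.05 read 0.07, 0.08 and 0.02 with quantile, upper-quartile and rescaled values. Without Namalwa DTEP replicate 3 the Namalwa change was 0.23 with adjusted p = 0.000566 in limma with Benjamini-Hochberg adjustment. BCL2A1 (chromosome 15, 79960889 to 79971446) is an anti-apoptotic NF-kB target. It rose in Namalwa from 9.66 ± 0.415 to 57.2 ± 3.21 TPM and read 87.1 ± 4.94 and 95.2 ± 6.63 TPM in SU-DHL16. The SU-DHL16 change of BCL2A1, 0.13 ± 0.06, did not pass (limma, Benjamini-Hochberg adjusted p = 0.115), but did with quantile, upper-quartile and rescaled values (0.0146, 0.00938 and 0.03) and without parental replicate 2 or DTEP replicate 1 (0.0325 and 0.0385). The difference between the lines was 2.32 ± 0.096 (adjusted p = 1.74e-08 in limma with Benjamini-Hochberg adjustment).

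BCL2L1, which encodes BCL-XL, rose by 0.35 ± 0.066 in Namalwa DTEP and fell by 0.21 ± 0.044 in SU-DHL16 DTEP. The fall no longer passed with quantile normalization or upper-quartile scaling (limma, Benjamini-Hochberg adjusted p = 0.111 and 0.12). The rise no longer passed without Namalwa parental replicate 3 (adjusted p = 0.055). The lines differed by 0.56 ± 0.075 (limma, Benjamini-Hochberg adjusted p = 0.000158). BCL2L2 rose by 0.61 ± 0.091 in Namalwa and read -0.11 ± 0.088 in SU-DHL16, or 0.003 with upper-quartile scaling, a difference of 0.71 ± 0.13 (limma, Benjamini-Hochberg adjusted p = 0.00125). Among BH3-only genes, which promote apoptosis, PMAIP1 rose from 52.6 ± 1.56 to 90.3 ± 6.46 TPM and BMF from 19.2 ± 0.243 to 29.4 ± 1.26 TPM in SU-DHL16 DTEP. In Namalwa neither passed, at -0.185 and 0.123 (limma, Benjamini-Hochberg adjusted p = 0.48 and 0.258). The lines differed by -0.952 for PMAIP1 and -0.465 for BMF (limma, Benjamini-Hochberg adjusted p = 0.00342 and 0.000917). Neither difference passed in the fit of all 18 libraries (adjusted p = 0.456 and 0.247). The SU-DHL16 change of PMAIP1, 0.77, was the same in the fit of all 18 libraries, where it no longer passed (limma, Benjamini-Hochberg adjusted p = 0.394). That fit also takes its spread from EJ-1, where replicate 3 read 481 TPM against 32.7 and 33.7 in replicates 1 and 2. HRK and BBC3 moved in opposite directions in the lines. HRK rose by 0.77 ± 0.13 in SU-DHL16, from 0.473 ± 0.174 TPM, and fell by 0.90 ± 0.086 in Namalwa, from 25 ± 1.66 TPM. BBC3 rose by 0.48 ± 0.14 in SU-DHL16 and fell by 0.67 ± 0.16 in Namalwa. The differences between lines were -1.66 ± 0.14 for HRK and -1.15 ± 0.24 for BBC3 (limma, Benjamini-Hochberg adjusted p = 5.12e-06 and 0.00326). The rise of BBC3 within SU-DHL16 no longer passed without DTEP replicate 2 or 3 (limma, Benjamini-Hochberg adjusted p = 0.0747 and 0.066). Its fall within Namalwa no longer passed without parental replicate 2 or 3, or DTEP replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0817, 0.0733 and 0.0657).

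BAX and BAD, an effector and a BH3-only gene, fell by 0.30 ± 0.054 and 0.20 ± 0.051 in SU-DHL16 DTEP. With upper-quartile scaling neither passed (limma, Benjamini-Hochberg adjusted p = 0.0587 and 0.207). BAD also no longer passed with quantile and rescaled values, in the fit of all libraries and without DTEP replicate 3 (0.116, 0.0589, 0.165 and 0.0533). BAK1, BCL2L11, BID and BIK did not pass the test in either line, and the sign of BAK1 in both lines and of BCL2L11 and BID in SU-DHL16 differed between scalings. In Namalwa, BCL2L11, BID, BIK and BAX passed without DTEP replicate 3, at 0.39, 0.18, -0.44 and -0.15 (limma, Benjamini-Hochberg adjusted p = 0.00584, 0.00737, 2.39e-05 and 0.0308). BCL2L11 and BID also passed in the fit of all libraries and BAX with rescaled values (limma, Benjamini-Hochberg adjusted p = 0.0245, 0.00711 and 0.0436). BCL2L10 and BOK were too low to be tested in any comparison.

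**Figure D1:**
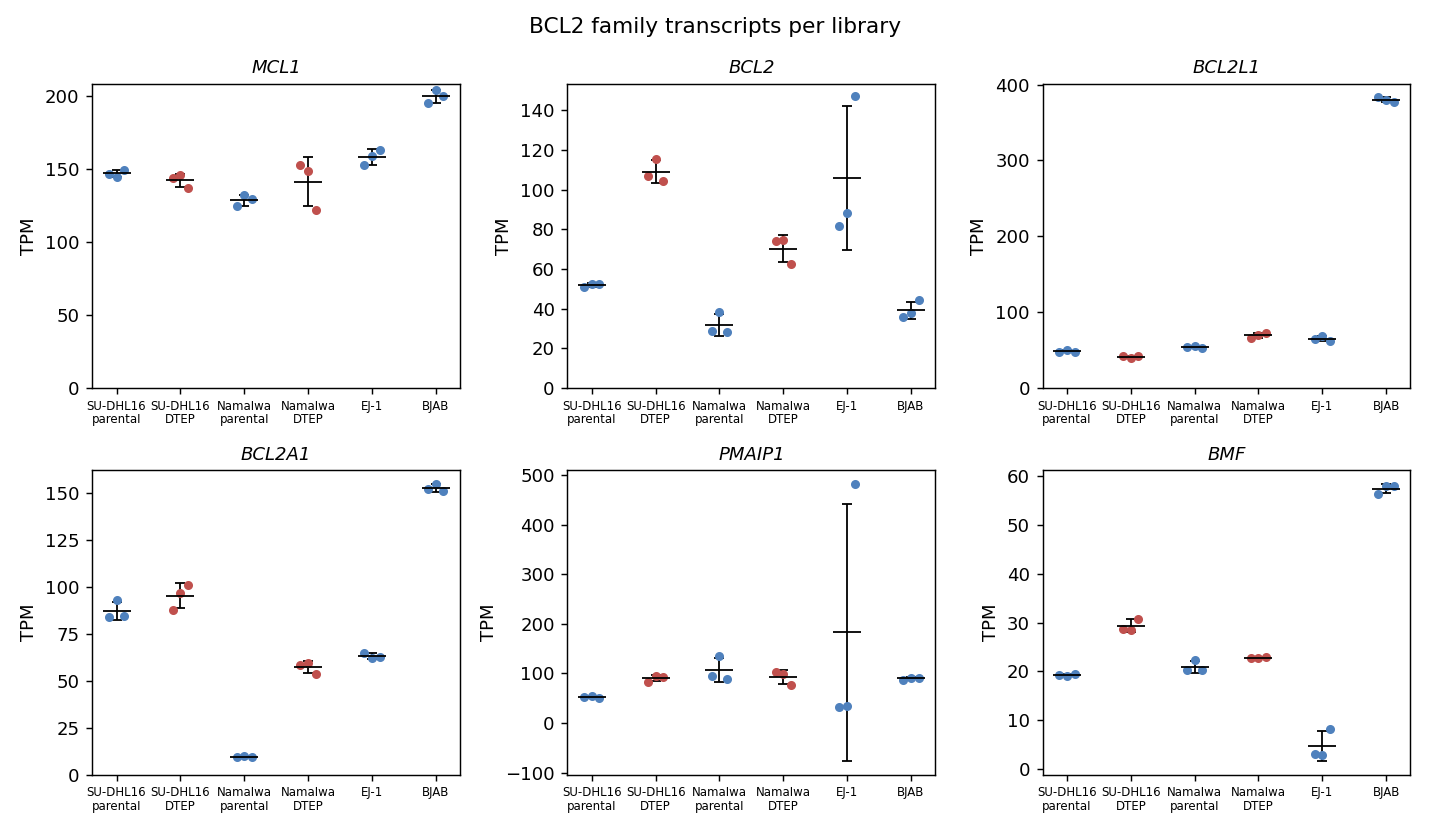
TPM of MCL1, BCL2, BCL2L1, BCL2A1, PMAIP1 and BMF in each of the 18 libraries, by group; points are libraries (DTEP in red), and bars are the mean and SD of 3. BCL2 lies higher in DTEP than in parental libraries of SU-DHL16 and Namalwa, BCL2A1 stands at 9.66 TPM in Namalwa parental and 57.2 in DTEP cells, and EJ-1 replicate 3 stands at 481 TPM of PMAIP1.

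In SU-DHL16, DTEP cells were compared with parental cells to see which transcripts accompany resistance to S63845. Interferon-induced transcripts led the rises. IFITM1, an interferon-induced membrane protein, rose from 2.46 ± 0.136 to 43.5 ± 0.941 TPM, and ISG15, a ubiquitin-like interferon product (chromosome 1, 1001138 to 1014540), from 17.4 ± 2.97 to 208 ± 12.4 TPM. OAS1, which makes 2'-5' oligoadenylates that activate RNase L (chromosome 12, 112906777 to 112933222), rose from 3.16 ± 0.059 to 37.8 ± 1.34 TPM. STAT5B, a cytokine-activated transcription factor, rose from 1.04 ± 0.0958 to 19.0 ± 0.936 TPM, and HTATIP2 from 0.414 ± 0.221 to 10.5 ± 1.13 TPM. The change was 3.68 ± 0.056 for IFITM1, 3.52 ± 0.099 for ISG15, 3.22 ± 0.054 for OAS1, 3.29 ± 0.073 for STAT5B and 3.03 ± 0.13 for HTATIP2, and OAS2 also rose by 3.03 ± 0.073.

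The largest falls in SU-DHL16 DTEP were smaller. EVL, a regulator of actin, fell by 2.11 ± 0.12, from 7.0 ± 0.543 to 0.857 ± 0.247 TPM. BACE2, an aspartic protease, fell by 1.92 ± 0.093, FBXO16 fell by 1.83 ± 0.13 and CTXN1 fell by 1.75 ± 0.14. RASSF6 fell by 1.68 ± 0.073, from 15.7 ± 1.47 to 4.21 ± 0.0865 TPM, and DNAJC5B by 1.64 ± 0.09. All 12 of these genes were chosen as called and without overlap between the replicates of both groups, so neither is a separate result. The largest adjusted p among them was 3.03e-05, for CTXN1 (limma, Benjamini-Hochberg).

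Of 22 tested interferon response genes, 21 rose and 1 fell, and 15 rose by at least 1 on the log2 scale. The counts were the same when adjusted over the list alone, and the median change was 1.98. IRF7, a transcription factor of this response, rose from 4.13 ± 0.28 to 30.6 ± 1.43 TPM. MX2, chosen after its values were seen, fell by 1.28 ± 0.076. The list was called by limma's camera with Benjamini-Hochberg adjusted p = 1.49e-26, and adjusted p = 0.0517 with an estimated correlation.

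Of 14 tested genes of MHC class II presentation, 12 rose and 2 fell, also when adjusted over the list alone. HLA-DRA and HLA-DRB1, the chains of HLA-DR, rose by 1.01 ± 0.035 each, HLA-DMB by 1.25 ± 0.064 and HLA-DPA1 by 0.59 ± 0.044. RFXAP and HLA-DOB, chosen after their values were seen, fell by 0.43 and 0.35. The camera test gave a Benjamini-Hochberg adjusted p = 1.12e-09 in limma, and adjusted p = 0.0517 with an estimated correlation. In MHC class I presentation, 8 of 15 genes rose and 1 fell, also when adjusted over the list alone. HLA-B, an antigen-presenting chain, rose by 2.32 ± 0.086, HLA-F by 1.73 ± 0.14, HLA-E by 0.64 ± 0.044 and TAP1, a peptide transporter, by 1.20 ± 0.074. Its camera adjusted p in limma was 1.8e-06 with Benjamini-Hochberg adjustment, and adjusted p = 0.0889 with an estimated correlation.

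Genes of MAPK and AP-1 signalling rose in 9 of 16 cases and fell in 1, also when adjusted over the list alone. ETV5 rose by 1.99 ± 0.06, from 6.12 ± 0.44 to 27.2 ± 0.635 TPM, DUSP5 by 1.18 ± 0.052, ETV4 by 0.98 ± 0.097 and IER2 by 0.83 ± 0.041. The list was called (limma camera, Benjamini-Hochberg adjusted p = 6.86e-07), with adjusted p = 0.0949 with an estimated correlation. Of 22 genes of the unfolded protein response and of ATF4, 11 rose and 5 fell, also when adjusted over the list alone. DDIT3, a stress-induced transcription factor, rose by 0.68 ± 0.052, ATF3 by 0.94 ± 0.14, VLDLR by 0.87 ± 0.12 and SHMT2 by 0.27 ± 0.032. Here camera gave adjusted p = 6.15e-05 (limma, Benjamini-Hochberg) and adjusted p = 0.207 with an estimated correlation.

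Of 20 genes of G1/S and replication, 0 rose and 17 fell, or 18 when adjusted over the list alone. UNG fell by 0.46 ± 0.054, CCNE1 by 0.39 ± 0.045 and MCM3 by 0.29 ± 0.035. Of 24 MYC target genes, 0 rose and 18 fell, also when adjusted over the list alone. MYC itself fell from 60.3 ± 3.42 to 43.2 ± 0.903 TPM, SRM, which makes spermidine, by 0.69 ± 0.045, NOP16 by 0.45 ± 0.042 and LDHA by 0.38 ± 0.035. Both lists had a camera adjusted p = 0.000101 in limma with Benjamini-Hochberg adjustment, and adjusted p = 0.318 and adjusted p = 0.311 with an estimated correlation. Replication-dependent histone transcripts, a sign of RNA quality in polyadenylated libraries, rose in 4 of 8 cases in the same libraries and fell in 0, also when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00271, and adjusted p = 0.256 with an estimated correlation).

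Heat shock genes fell in 10 of 13 cases and rose in 2, also when adjusted over the list alone. The chaperones HSPH1, HSPE1, HSPD1 and HSP90AB1 fell by 0.58 ± 0.047, 0.41 ± 0.049, 0.32 ± 0.031 and 0.32 ± 0.035. BAG3 and HSPB1, chosen after their values were seen, rose by 0.67 and 0.61. The list had a camera adjusted p = 0.0214 (limma, Benjamini-Hochberg) and adjusted p = 0.44 with an estimated correlation. Of 30 ribosomal protein genes, 15 rose and 0 fell, also when adjusted over the list alone, with a median of 0.11. RPL4 rose by 0.40 ± 0.033, RPLP1 by 0.37 ± 0.045, RPLP0 by 0.21 ± 0.038 and RPL10A by 0.19 ± 0.033. RPLP0 read -0.02 with quantile normalization. Camera gave adjusted p = 1.31e-08 (limma, Benjamini-Hochberg), and adjusted p = 0.151 with an estimated correlation. With quantile normalization this list was no longer called (adjusted p = 0.179).

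Of 11204 genes tested in SU-DHL16, 168 were called, 129 higher and 39 lower in DTEP cells. Without parental replicate 2 or 3, when genes below 1 TPM in every DTEP library went untested, the number lower was 22 and 25. With rescaled values 198 were higher. By adjusted p alone 4847 passed, 1314 higher and 3533 lower, so most falls were small. The groups did not overlap in 6169 genes (55.1%). The median change of all genes was -0.09, and 0.02 with upper-quartile scaling, so falls of about 0.1 lie within what scaling moves. Of 31 lists tested, 18 were called, 11 up and 7 down. With an estimated correlation camera called 0, and 7 had an unadjusted p below 0.05. Ribosomal protein transcripts took 29.3% to 30.8% of SU-DHL16 parental libraries and 32.9% to 33.7% of DTEP libraries.

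In Namalwa, the same comparison gave other leading genes. CKM, the creatine kinase of muscle, rose from 6.66 ± 0.922 to 115 ± 5.79 TPM in DTEP cells, and CCL22, a chemokine that attracts T cells (chromosome 16, 57358772 to 57366190), from 9.04 ± 0.535 to 85.1 ± 12.5 TPM. HSPA1A, an inducible HSP70 chaperone with a near-identical copy, rose from 0.648 ± 0.112 to 23.1 ± 4.25 TPM. RGS13, a germinal centre regulator of G-protein signalling (chromosome 1, 192636138 to 192660306), fell from 45.3 ± 0.964 to 0.418 ± 0.3 TPM. RAG1 and RAG2, the recombinase of antigen receptor genes, fell from 28.5 ± 0.47 to 1.25 ± 0.187 and from 28.8 ± 0.611 to 2.46 ± 0.599 TPM.

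The rises were 3.92 ± 0.1 for CKM, 3.86 ± 0.14 for HSPA1A, 3.17 ± 0.12 for ATP4B, 3.09 ± 0.12 for CCL22, 2.84 ± 0.095 for DHRS3 and 2.82 ± 0.14 for DMKN. The falls were -5.05 ± 0.16 for RGS13, -3.93 ± 0.1 for BCHE, a cholinesterase, and -3.72 ± 0.095 for RAG1. They were -3.47 ± 0.15 for LY6E, -3.12 ± 0.12 for VPREB1, part of the surrogate light chain, and -3.12 ± 0.13 for RAG2. These 12 were likewise chosen as called genes without overlap between the groups, so neither is a separate result. The largest adjusted p was 3.46e-05, for DMKN (limma, Benjamini-Hochberg).

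Interferon response genes rose in Namalwa DTEP as well. Of 27 tested, 24 rose and 0 fell, or 25 rose when adjusted over the list alone, with a median of 0.83. IFI6 rose from 35.1 ± 0.647 to 181 ± 32.2 TPM, IFI44L from 17 ± 0.426 to 78.2 ± 11.6 and IFIT3 by 1.27 ± 0.078. OAS2, at 0.30 ± 0.1, did not pass. Camera called the list (limma, Benjamini-Hochberg adjusted p = 1.2e-12), also at adjusted p = 0.0355 with an estimated correlation.

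NF-kB target genes rose in 12 of 21 cases and fell in 1, or 13 and 1 when adjusted over the list alone. EBI3, a cytokine subunit, rose from 11.9 ± 0.763 to 84.0 ± 1.16 TPM, and TRAF1, a signalling adaptor, from 2.99 ± 0.123 to 23.3 ± 0.651 TPM, beside CCL22 and BCL2A1. The camera test of this list had an adjusted p = 9.76e-05 (limma, Benjamini-Hochberg) and adjusted p = 0.0933 with an estimated correlation. Heat shock genes rose in 12 of 14 cases and fell in 0, or 13 when adjusted over the list alone, with a median of 0.50. DNAJB1 rose by 0.85 ± 0.048, HSPH1 by 0.77 ± 0.045 and DNAJA1 by 0.60 ± 0.046. This list was called by camera (limma, Benjamini-Hochberg adjusted p = 7.98e-07), also at adjusted p = 0.0426 with an estimated correlation.

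MHC class II genes rose in 10 of 15 cases and fell in 0, also when adjusted over the list alone. CD74, the invariant chain, rose from 1627 ± 56.0 to 2788 ± 70.5 TPM, HLA-DOB by 1.33 ± 0.14, HLA-DQA1 by 0.84 ± 0.1 and HLA-DPA1 by 0.45 ± 0.059. Camera gave adjusted p = 0.00129 (limma, Benjamini-Hochberg) and adjusted p = 0.146 with an estimated correlation.

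Germinal centre and plasma-cell genes were among the lists called down. Of 13 germinal centre genes, 8 fell and 0 rose, or 8 fell and 1 rose when adjusted over the list alone, with a median of -0.45. BCL6, the repressor that maintains germinal centre cells, fell by 0.56 ± 0.077 and GCSAM by 0.53 ± 0.09. Of 13 plasma-cell genes, 7 fell and 2 rose, or 7 and 3 when adjusted over the list alone. XBP1, a transcription factor of secretory cells, fell from 219 ± 5.18 to 91.0 ± 7.84 TPM, MZB1 by 1.05 ± 0.066 and FKBP11 by 0.65 ± 0.051, while SLAMF7 rose by 1.31 ± 0.12. The camera tests had adjusted p = 2.75e-05 and 0.00237 (limma, Benjamini-Hochberg), with adjusted p = 0.291 and adjusted p = 0.188 with an estimated correlation. Of 20 genes of B-cell identity and the B-cell receptor, 7 rose and 3 fell, also when adjusted over the list alone, and this list was not called (limma camera, Benjamini-Hochberg adjusted p = 0.775).

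MYC fell from 236 ± 4.99 to 102 ± 3.95 TPM in Namalwa DTEP. Of 24 MYC target genes, 10 fell and 0 rose, or 13 fell when adjusted over the list alone. PPAT fell by 0.59 ± 0.1, FBL by 0.39 ± 0.067 and ODC1 by 0.29 ± 0.044. Of 30 ribosomal protein genes, 18 fell and 1 rose, or 22 and 1 when adjusted over the list alone, while these transcripts took 29.3% to 30.2% of parental and 26% to 26.5% of DTEP libraries, with RPSA at -0.43 ± 0.043 and RPL10A at -0.34 ± 0.038. Both lists were called by camera (limma, Benjamini-Hochberg adjusted p = 2.94e-09 and 1.27e-11), also at adjusted p = 0.037 and adjusted p = 0.0426 with an estimated correlation. Histone transcripts, the sign of RNA quality, rose in 5 of 8 cases and fell in 0, also when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00201, and adjusted p = 0.101 with an estimated correlation).

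Some markers of other cell types were also higher in Namalwa DTEP cells, at low levels. Of 16 myeloid markers 6 were tested, and 5 rose and 0 fell. Of 15 epithelial and stromal markers 5 were tested, and 3 rose and 0 fell. These counts were the same when adjusted over the list alone. ITGAM and TYROBP went from 0.247 ± 0.0247 to 1.74 ± 0.121 and from 0.294 ± 0.115 to 2.70 ± 0.843 TPM, while CSF1R rose by 1.06 ± 0.13 and CD68 by 0.78 ± 0.15. COL1A1, a collagen chain, rose from 0.839 ± 0.0978 to 8.25 ± 1.19 TPM, VIM, which B cells can also express, by 1.58 ± 0.086 and PDGFRB by 0.64 ± 0.099. PECAM1, at 0.23 ± 0.11, did not pass. The camera tests had adjusted p = 0.0082 and 0.0125 (limma, Benjamini-Hochberg), with adjusted p = 0.146 for each with an estimated correlation. Of 5 T and NK cell markers, 3 rose and 1 fell, also when adjusted over the list alone, and that list was not called (limma camera, Benjamini-Hochberg adjusted p = 0.318). Without any 1 of the DTEP replicates, fewer than 5 members of the myeloid and the epithelial and stromal list remained, and these were not tested. Members such as ITGAM and TYROBP met the filter only through their DTEP values, and could hardly have counted as falls.

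Of 12462 genes tested in Namalwa, 459 were called, 318 higher and 141 lower in DTEP cells. Without parental replicate 1, 2 or 3, when genes below 1 TPM in every DTEP library went untested, the number lower was 93, 87 and 88. With quantile normalization 202 were higher. By adjusted p alone, the threshold of the list counts, 3288 passed, 2421 higher and 867 lower. The groups did not overlap in 5824 genes (46.7%). The share of called genes that were higher was 69.3%, and 53.9% with quantile normalization. Namalwa DTEP replicate 3 differed from its group by a root mean square of 0.24 on the log2 scale, against 0.17 and 0.14 for replicates 1 and 2. Of 34 lists tested, 17 were called, 10 up and 7 down. With an estimated correlation 4 were called, the interferon, MYC target, ribosomal protein and heat shock lists.

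The lines shared a group of rises. Of 10571 genes tested in both, 17 were called higher in DTEP cells of both lines, against 1.3 for independent lists (Fisher's exact test across genes, 1-sided p = 8.07e-15; genes are not independent replicates). IFI6, ISG15, IFI35 and IFIT3, all interferon-induced, and IL4I1, an amino acid oxidase of immune cells, led by the rule. IFI6 changed by 2.94 ± 0.1 in SU-DHL16 and 2.32 ± 0.12 in Namalwa, ISG15 by 3.52 and 1.90, IFI35 by 1.92 and 1.5, IFIT3 by 2.44 and 1.27, and IL4I1 by 1.21 and 2.34. Only 2 genes were called lower in both, against 0.158 for independent lists (Fisher's exact test, 1-sided p = 0.0107). These were ARPP21 and NOL4, chosen after their values were seen. ARPP21 read -1.32 ± 0.12 in SU-DHL16 and -1.85 ± 0.091 in Namalwa. NOL4 stood at 1.46 ± 0.0648 TPM in SU-DHL16 parental cells and was listed at 0 in DTEP cells, and fell by 1.20 ± 0.14 in Namalwa. The counts of 17 and 2 moved when a replicate was left out, in part because the filter still asked for 3 libraries at 1 TPM. IFIT3, at 0.318 ± 0.0851 TPM in SU-DHL16 parental cells, no longer met it without any 1 SU-DHL16 DTEP replicate. Without SU-DHL16 DTEP replicate 1, 2 or 3 the number called higher was 11, 10 and 11, and without any 1 SU-DHL16 parental replicate 0 were called lower. Without any 1 Namalwa parental replicate, 1 was called lower. ARPP21 and NOL4 in SU-DHL16 DTEP, and NOL4 in Namalwa DTEP, lay below 1 TPM in every library, so that without a parental replicate they no longer met the filter.

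LTB, a cytokine of the TNF family, was among 5 genes called in opposite directions. Of these, 3 were higher in SU-DHL16 and lower in Namalwa DTEP, against 0.741 for independent lists (Fisher's exact test across genes, 1-sided p = 0.0379). The other 2 went the opposite way, against 0.277 (Fisher's exact test, 1-sided p = 0.0308). LTB rose from 206 ± 8.12 to 519 ± 11.9 TPM in SU-DHL16 and fell from 11.6 ± 1.16 to 3.44 ± 0.463 TPM in Namalwa. Its difference between the lines was -2.83 ± 0.12 (limma, Benjamini-Hochberg adjusted p = 1.74e-08). Over all 10571 genes, the changes in both lines correlated across genes with Pearson's r of 0.184 and Spearman's rho of 0.131. Without the interferon list these were 0.158 and 0.126.

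**Figure D2:**
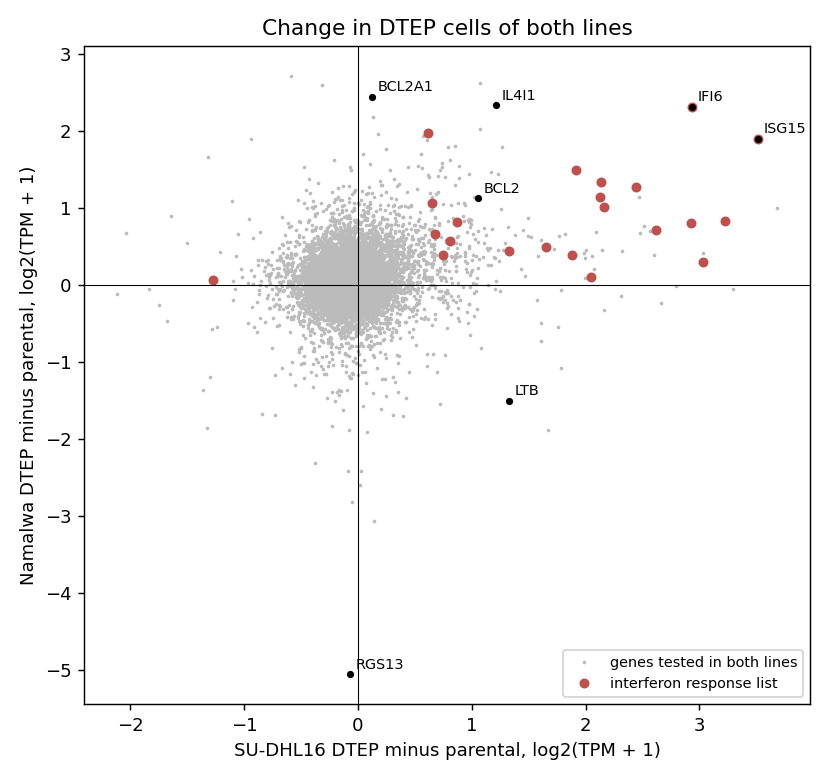
Change of each of the 10571 genes tested in both lines, SU-DHL16 DTEP minus parental on the x axis and Namalwa DTEP minus parental on the y axis, in log2(TPM + 1). Interferon response genes (red) lie mostly to the upper right, with ISG15 at 3.52 and 1.90, while RGS13 fell by 5.05 in Namalwa.

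The test of the difference between the effects covered 13157 genes, of which 10571 were also tested within both lines. It called 608, with 368 higher and 240 lower in Namalwa relative to SU-DHL16. The share higher was 60.5%, against 45.7% with quantile normalization and 47.2% with upper-quartile scaling. The median difference was 0.16, and 0.003, 0.015 and 0.039 with quantile, upper-quartile and rescaled values, so directions depend on the scaling. By adjusted p alone 4370 genes passed, 3316 upward and 1054 downward. Of 14 heat shock genes 12 differed upward and 0 downward, with a median of 0.76, and of 15 germinal centre genes 0 upward and 11 downward, or 1 and 11 when adjusted over the list alone, with a median of -0.52 (limma camera, Benjamini-Hochberg adjusted p = 2.85e-07 and 6.08e-08). Both were lost at adjusted p = 0.0703 and adjusted p = 0.123 with an estimated correlation. Of 34 lists tested 17 were called, 6 up and 11 down, and the interferon, ribosomal protein and unfolded protein response lists were also called with an estimated correlation. Lists of this difference were not tested with other scalings, so how far their calls depend on scaling is unknown.

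**Figure D3:**
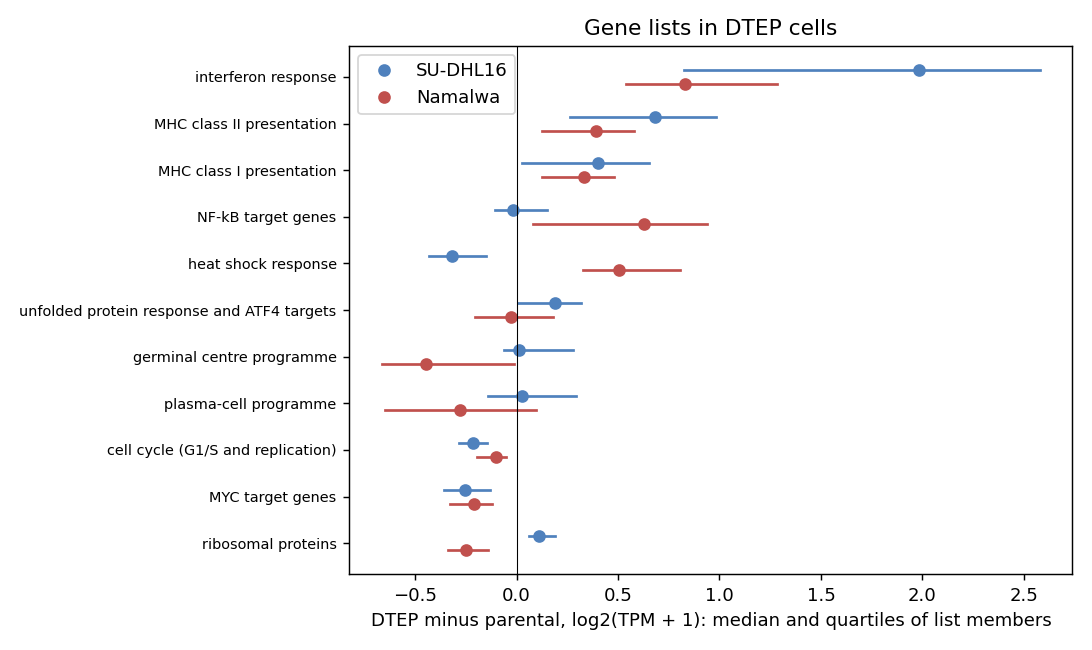
Median change of 11 gene lists in DTEP against parental cells of SU-DHL16 (blue) and Namalwa (red), in log2(TPM + 1); points are medians and lines span the quartiles of tested members. The interferon list lies at 1.98 and 0.83, and heat shock genes lie at -0.32 and 0.50; with quantile normalization the ribosomal proteins of SU-DHL16 were no longer called.

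BJAB and EJ-1 have no partner of their own, and were compared because BJAB is labelled resistant and EJ-1 naive. This sets 2 cell lines against each other, so the line and its drug response cannot be told apart. EEF1A2, a translation elongation factor (chromosome 20, 63488012 to 63499322), stood at 721 ± 12.2 TPM in BJAB and 0.868 ± 0.369 in EJ-1. RGS13 stood at 389 ± 15.1 and 0.486 ± 0.525 TPM, and IL1RN, the interleukin-1 receptor antagonist, at 199 ± 0.562 and 0.0504 ± 0.0489 TPM. CYB5A, cytochrome b5, stood at 0.103 ± 0.0901 TPM in BJAB and 237 ± 7.62 in EJ-1, and S100A10 at 0.114 ± 0.122 and 185 ± 2.07 TPM.

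Among the leading genes of shared sequence, HLA-DQB1 and HLA-DRB1 were 8.49 ± 0.051 and 7.64 ± 0.27 higher in BJAB on the log2 scale. The cancer-testis gene CTAG2 was lower, at -8.14 ± 0.12, and BEX3 at -7.49 ± 0.073. MAGEA6 was listed at 0 in all BJAB libraries and stood at 181 ± 7.92 TPM in EJ-1. The largest adjusted p among the 10 leading genes was 7.27e-08, for HLA-DRB1 (limma, Benjamini-Hochberg).

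Within the BCL2 family, BCL2L1 stood at 380 ± 3.45 TPM in BJAB and 64.9 ± 3.5 in EJ-1, a difference of 2.53 ± 0.041 (limma, Benjamini-Hochberg adjusted p = 1.8e-09). BCL2A1 was 1.26 ± 0.031 and BMF 3.49 ± 0.3 higher, and BIK was 3.02 ± 0.23 higher. BCL2 was lower in BJAB, at -1.36 ± 0.21, as were BAX at -1.35 ± 0.046 and BID at -1.69 ± 0.055. EJ-1 replicate 3 read 147 TPM of BCL2, against 81.8 and 88.5 in replicates 1 and 2. It read 8.17 TPM of BMF against 3.06 and 2.79, and 3.80 TPM of BIK against 1.52 and 1.78. The sizes of the BCL2, BMF and BIK differences thus depend in part on that library. MCL1 stood at 200 ± 4.48 and 158 ± 5.32 TPM, and no longer passed with quantile normalization, at 0.03 (limma, Benjamini-Hochberg adjusted p = 0.37). PMAIP1 read 481 TPM in EJ-1 replicate 3 against 32.7 and 33.7 in the others. Its difference was 0.14 ± 0.93 (limma, Benjamini-Hochberg adjusted p = 0.897), -0.09, -0.04 and -0.04 with quantile, upper-quartile and rescaled values, -0.51 and -0.49 without EJ-1 replicate 1 or 2, and 1.41 without replicate 3 (adjusted p = 2.72e-09).

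MHC class I genes were higher in BJAB in 15 of 16 cases and lower in 1, also when adjusted over the list alone. HLA-E, HLA-B, B2M and the immunoproteasome subunit PSMB9 were higher by 2.85 ± 0.033, 3.90 ± 0.12, 1.77 ± 0.031 and 1.41 ± 0.038. Of 21 JAK-STAT and cytokine genes, 19 were higher and 2 lower, also when adjusted over the list alone. IL10, an anti-inflammatory cytokine, stood at 54.2 ± 0.782 and 0.328 ± 0.0393 TPM, STAT5A and IL2RG were 3.29 ± 0.068 and 2.23 ± 0.032 higher, and PIM1 was lower at -2.85 ± 0.046. G2/M genes were higher in 19 of 20 cases and lower in 1, also when adjusted over the list alone, with KIF20A at 2.16 ± 0.045, CDC20 at 1.14 ± 0.035, TPX2 at 1.11 ± 0.034 and CCNA2 at 0.93 ± 0.033. These lists had camera adjusted p = 0.00149, 0.00154 and 0.00096 (limma, Benjamini-Hochberg), with adjusted p = 0.612 for each with an estimated correlation. Histone transcripts, the sign of RNA quality, were higher in 7 of 8 cases and lower in 0, or 8 higher when adjusted over the list alone, and the list was not called (limma camera, Benjamini-Hochberg adjusted p = 0.102).

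Glycolysis and hypoxia genes were lower in BJAB. Of 23 glycolysis genes 18 were lower and 5 higher, and of 16 hypoxia genes 13 were lower and 1 higher, also when adjusted over the list alone. LDHA, lactate dehydrogenase, stood at 543 ± 11 and 1459 ± 34.9 TPM, PFKFB4 and ALDOC at -4.47 ± 0.1 and -2.50 ± 0.063, while SLC2A3, a glucose transporter, was 3.35 ± 0.089 higher. BNIP3, a mitochondrial protein induced by hypoxia, stood at 0.347 ± 0.199 and 222 ± 6.95 TPM, with ANKRD37 at -2.98 ± 0.041, ADM at -2.02 ± 0.047 and P4HA1 at -1.32 ± 0.035. Both lists had a camera adjusted p = 0.000143 (limma, Benjamini-Hochberg), with adjusted p = 0.612 for each with an estimated correlation.

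Of 16 myeloid markers 6 were tested, and these 6 were higher in BJAB, also when adjusted over the list alone. CST3 stood at 47.7 ± 3.52 TPM and was listed at 0 in EJ-1, and ITGAM stood at 27.6 ± 1.17 and 0.0245 ± 0.0289 TPM. CD68 and CSF1R were 1.86 ± 0.13 and 1.41 ± 0.085 higher. The list had a camera adjusted p = 0.0363 (limma, Benjamini-Hochberg), with adjusted p = 0.612 with an estimated correlation. Without any 1 of the BJAB replicates fewer than 5 members remained, and the list was not tested. Members such as CST3 and ITGAM met the filter only through their BJAB values, and could hardly have counted as lower. Of 5 epithelial and stromal markers, 2 were higher and 1 lower, also when adjusted over the list alone, and that list was not called (limma camera, Benjamini-Hochberg adjusted p = 0.86).

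Of 12841 genes tested, 4032 were called, 2706 higher and 1326 lower in BJAB. Without EJ-1 replicate 1, 2 or 3 the number lower was 795, 750 and 774, and without BJAB replicate 2 or 3 the number higher was 1758 and 1788. In these fits, genes below 1 TPM in every library of the intact line went untested. By adjusted p alone, the threshold of the list counts, 10619 passed, 6661 higher and 3958 lower. Many genes of any list would thus pass, more often higher than lower. The groups did not overlap in 10844 genes (84.4%). The share of called genes that were higher was 67.1%, and 50.9% with quantile normalization. The median difference of all genes was 0.22, and -0.04, 0.06 and 0.07 with quantile, upper-quartile and rescaled values. Of 33 lists tested, 12 were called, 7 up and 5 down, or 3 down without BJAB replicate 1 or 2 and with quantile normalization. With an estimated correlation camera called 0, and 1 had an unadjusted p below 0.05. EJ-1 replicate 3 held 20 genes of at least 5 TPM that lay below 0.5 TPM in both other EJ-1 replicates, against 0 to 2 such genes in every other library.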

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

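Of the tests in this part, those of GC content and length in Namalwa DTEP replicate 3, of other lines in EJ-1 replicate 3 and of both explanations of the interferon rise were chosen only after the result was seen.

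The DTEP effect differed between the lines in 608 genes by limma's test of the difference with Benjamini-Hochberg adjustment. Of 100 splits of the libraries within their lines, the real one included, 2 gave as many genes. Mixing the groups of a line removed that line's own effect, leaving at most 1 gene called in it, so these splits do not test a difference between the lines. With both lines mixed they gave 0 to 2 genes, with SU-DHL16 alone intact 128 to 182 and with Namalwa alone intact 413 to 469. The highest other reached 798 and exchanged the parental and DTEP labels of Namalwa alone, so that the effects of both lines add. Values below are the Namalwa change minus the SU-DHL16 change on the log2 scale, and each gene passed that test. The leading genes were chosen by their change within a line, which the difference in part repeats.

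Of the genes that led in SU-DHL16, IFITM1 differed by -2.675, ISG15 by -1.613, STAT5B by -3.349, OAS1 by -2.39, OAS2 by -2.73 and HTATIP2 by -2.606. Among those that fell there, EVL differed by 1.999, BACE2 by 1.887, FBXO16 by 1.788, CTXN1 by 1.498, RASSF6 by 1.209 and DNAJC5B by 2.551. BACE2 stood at 0.141 and 0.108 TPM in Namalwa parental and DTEP cells and could hardly fall there, so its difference repeats the SU-DHL16 fall. Of the genes that led in Namalwa, CKM differed by 3.862, HSPA1A by 3.766, ATP4B by 3.195, CCL22 by 3.185, DHRS3 by 2.845 and DMKN by 2.648. All of these had means below 0.5 TPM in both SU-DHL16 groups, so their difference is close to the Namalwa change alone. RGS13 differed by -4.988, BCHE by -3.925, RAG1 by -3.754, LY6E by -3.585, VPREB1 by -3.381 and RAG2 by -3.12. RGS13 stood at 465 and 444 TPM in SU-DHL16 parental and DTEP cells. The others had means below 0.5 TPM in both and could hardly fall there, so their difference repeats the Namalwa fall. Of genes called in both lines, IFIT3 differed by -1.167, IL4I1 by 1.126 and LTB by -2.829. In the BCL2 family, BCL2A1 differed by 2.323, BBC3 by -1.148 and HRK by -1.664.

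Among gene lists, the median difference was -0.613 for the interferon response, -0.375 for ribosomal proteins and -0.263 for the unfolded protein response and ATF4 targets. With an estimated correlation limma's camera gave these Benjamini-Hochberg adjusted p = 0.0144, 0.0139 and 0.0139. None of these list differences was tested with other scalings.

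Of 27 interferon response genes, 15 changed further upward on the log2 scale in SU-DHL16 DTEP and 4 in Namalwa DTEP, or 17 and 7 when adjusted over the list alone. SU-DHL16 started from lower levels in ISG15, which went from 17.4 to 208 TPM there and from 115 to 445 TPM in Namalwa. RNA of Namalwa in the SU-DHL16 DTEP libraries would need a share of 32.1%, whereas 168 Namalwa transcripts reached a median share of 0.046%. The median change of the interferon list was at least 2.001 under quantile normalization and upper-quartile scaling. These moved the SU-DHL16 median of all genes only from -0.092 to -0.032 and 0.019. They could hardly have removed a change of that size, so the test of scaling adds little beyond showing that its shifts are small. A difference between the resistant cells of these lines stays open as a hypothesis and was not tested.

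Namalwa DTEP replicate 3 stood apart from replicates 1 and 2. Its deviation from the mean of the other replicates followed GC content across genes, with a Spearman rho of 0.744, against -0.04 for transcript length. Replicates 1 and 2 read -0.695 and -0.599, each set against a mean that holds replicate 3, and in the other groups the largest was 0.193. Genes are not independent replicates, and 95.1% of 14137 genes had a GC value. A bias by GC content in that library is a candidate explanation, and no biological explanation was tested.

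EJ-1 replicate 3 held 20 transcripts that the other EJ-1 replicates lacked. RNA of a mantle cell lymphoma line is argued against by CCND1 and SOX11, whose larger excess was -0.0168 TPM. RNA of another line of the series as the source of all 20 is argued against by the 6 that lay above 2 times the highest other group, among them ANXA1 at 28.2 against 2.61 TPM, although all 6 were also raised by at least 1 TPM in Namalwa parental replicate 2 over both other replicates. For the remaining 14, that source would need a median share of 17.8%, and the highest found was 1.52% (Namalwa), above the 1% bound set for excluding it, so it cannot be told apart. The separation into 6 and 14 was added after that bound was passed, and neither another outside source nor a biological explanation was tested.

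The 6 libraries of a comparison allow 10 splits, tested with limma, too few for a share under 0.05. In SU-DHL16 the real split gave 168 genes and the highest other 1, and 18 against 14 lists. In Namalwa these were 459 against 1 gene and 17 against 10 lists, and for BJAB against EJ-1 they were 4032 against 0 genes and 12 against 10 lists. Of the 100 splits within lines, 1 gave as many genes called higher in both lines (17, highest other 3) and 2 as many called lower (2, highest other 2). A line with mixed groups called at most 1 gene, which leaves almost nothing to overlap, so these splits do not test either count. The highest other came from the exchange of the Namalwa labels.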

How the results depend on the processing

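The fit without a pair of Namalwa libraries that stand apart was chosen only after the data were seen. The cause of a change was not tested unless given.

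With a pseudocount of 0.1 the counts called were 302 in SU-DHL16, 708 in Namalwa, 1015 for the difference between lines, 36 higher in both and 4 lower in both. With a filter of 5 TPM, which tests fewer genes, they were 102, 297, 10 higher in both and 0 lower in both. By adjusted p alone, with no minimum change, they were 4847, 3288, 4370, 10619 for BJAB against EJ-1, 396 higher in both and 293 lower in both. With an estimated correlation 0, 4 and 0 lists were called in SU-DHL16, Namalwa and BJAB against EJ-1. Leaving out 1 replicate, with the filter still at 3 libraries, gave 10 to 18 genes higher in both lines and 0 to 2 lower. Without the Namalwa pair, 340 genes were called in Namalwa, 86 of them lower, 17 higher in both and 1 lower.

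The replicate numbers did not pair the libraries: correlations of same-numbered deviations lay between -0.073 and 0.064, and not every library correlated best with its own number. With the replicate block 168, 465, 608 and 4033 genes were called in the 4 comparisons, and 17, 17 and 9 lists in SU-DHL16, Namalwa and BJAB against EJ-1. The block ended the calls of glycolysis and oxidative phosphorylation in SU-DHL16 (limma camera, Benjamini-Hochberg adjusted p = 0.059 and 0.0593), and of p53 targets, heat shock and myeloid markers in BJAB against EJ-1 (0.0506, 0.0702 and 0.0506).

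Signs changed for genes that did not pass, RPLP0 excepted. In SU-DHL16, values with quantile, upper-quartile and rescaled data were 0.065, 0.075 and 0.02 for MCL1 and 0.05, 0.084 and 0.031 for BCL2L11, which ran from -0.08 to 0.009 with 1 replicate left out. BAK1 read 0.004 and 0.02 and BID 0.013 and 0.032 with quantile and upper-quartile values, BCL2L2 0.003 with upper-quartile scaling, and RPLP0 -0.02 with quantile normalization. In Namalwa, BAK1 read -0.011, -0.01 and -0.016. In BJAB against EJ-1 it read -0.069, -0.072 and -0.076, PMAIP1 -0.094, -0.043 and -0.043, and BAD -0.172, -0.135 and -0.14. With 1 replicate left out PMAIP1 ran from -0.51 to 1.409 and BAD from -0.021 to 0.109. For the difference between lines, BCL2 read -0.09 and -0.062 with upper-quartile and rescaled values, and with quantile and upper-quartile values BAX read -0.013 and -0.01 and BAK1 -0.016 and -0.004. Of 3013 named values under the alternatives, 2920 kept direction and side of the adjusted p threshold. Another 35 no longer passed the test, 24 newly passed it, and 34 changed sign.

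In SU-DHL16 the oxidative phosphorylation and cholesterol lists were lost with quantile normalization (limma camera, Benjamini-Hochberg adjusted p = 0.856 and 0.179). Depth is unknown, so what it limits cannot be stated.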

Other observations

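The test of the run of silent genes in BJAB was chosen only after the result was seen.

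Lists not yet described were called by limma's camera with Benjamini-Hochberg adjustment, and each was lost with an estimated correlation. In SU-DHL16 DTEP, 14 of 20 genes of mitochondrial dynamics fell and 0 rose (adjusted p = 0.00106, and adjusted p = 0.248 with an estimated correlation). Of 13 adhesion genes 6 rose and 1 fell (adjusted p = 0.000105, and adjusted p = 0.0949 with an estimated correlation), and of 20 p53 targets 8 rose and 4 fell (adjusted p = 0.00615, and adjusted p = 0.151 with an estimated correlation). These counts were the same when adjusted over the list alone. Germinal centre genes rose in 6 of 14 cases and fell in 1, and JAK-STAT genes rose in 5 of 15 and fell in 2, also when adjusted over the list alone. Their adjusted p = 0.0121 and 0.0101 in limma's camera with Benjamini-Hochberg adjustment, and adjusted p = 0.44 and adjusted p = 0.248 with an estimated correlation. Cholesterol and fatty acid synthesis genes fell in 13 of 22 cases and rose in 1, or 14 and 1 when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0134, and adjusted p = 0.565 with an estimated correlation). Glycolysis genes fell in 14 of 23 and rose in 4, or 15 and 4 when adjusted over the list alone, and oxidative phosphorylation genes fell in 13 of 30 and rose in 1, also when adjusted over the list alone. Both had adjusted p = 0.283 with an estimated correlation, against adjusted p = 0.0331 and 0.0459 (limma camera, Benjamini-Hochberg). The glycolysis call was lost without parental replicate 1 or 3, or DTEP replicate 1 or 2 (0.0528, 0.0523, 0.0676 and 0.0789), and that of oxidative phosphorylation without parental replicate 1 or 3 or any DTEP replicate (0.128, 0.0925, 0.0723, 0.102 and 0.051).

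In Namalwa DTEP, 4 of 5 anti-apoptotic BCL2 family members rose and 0 fell, also when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00298, and adjusted p = 0.177 with an estimated correlation). MHC class I genes rose in 8 of 16 cases and fell in 1, or 9 and 1 when adjusted over the list alone (adjusted p = 0.0131, and adjusted p = 0.313 with an estimated correlation). Of 20 p53 targets 6 fell and 3 rose, or 8 and 3 when adjusted over the list alone (adjusted p = 0.00563, and adjusted p = 0.237 with an estimated correlation). G1/S genes fell in 3 of 20 cases and rose in 0, and cholesterol genes fell in 5 of 22 and rose in 1, also when adjusted over the list alone (adjusted p = 0.000315 and 0.000804, and adjusted p = 0.0821 and adjusted p = 0.0933 with an estimated correlation). MAPK and AP-1 genes rose in 8 of 13 cases and fell in 0, also when adjusted over the list alone (adjusted p = 0.0392, and adjusted p = 0.18 with an estimated correlation), a call lost without DTEP replicate 1, 2 or 3 (0.065, 0.0988 and 0.565). For the difference between the lines, the JAK-STAT list had a median of 0.04, a mean of -0.22 and a test pointing down (adjusted p = 0.0369, and adjusted p = 0.229 with an estimated correlation).

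In BJAB against EJ-1, interferon response genes were higher in 18 of 23 cases and lower in 0, and MHC class II genes higher in 14 of 15 and lower in 1 (limma camera, Benjamini-Hochberg adjusted p = 0.00329 and 0.00203). These and the other lists of this paragraph had adjusted p = 0.612 with an estimated correlation, and the same counts when adjusted over the list alone. Ribosomal protein genes were lower in 20 of 30 cases and higher in 4 (adjusted p = 0.000145), but not called with quantile normalization (adjusted p = 0.404). MYC targets were lower in 15 of 24 cases and higher in 7 (adjusted p = 0.0292), a call lost without BJAB replicate 1, 2 or 3 (0.0522, 0.0658 and 0.0586). Heat shock genes were higher in 11 of 14 and lower in 3 (adjusted p = 0.0485), a call lost without EJ-1 replicate 2 or 3 (0.0518 and 0.0915). The p53 list, lower in 14 of 22 and higher in 6, had a median of -0.34, a mean of 0.01 and a test pointing down (adjusted p = 0.0485). It was lost with quantile normalization (0.205) and without EJ-1 replicate 3 or BJAB replicate 1 or 2 (0.0555, 0.0522 and 0.0581).

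Of the 20 transcripts private to EJ-1 replicate 3, 14 lay in Namalwa parental replicate 2 at least 1 TPM above both other Namalwa parental replicates. All 6 that exceeded 2 times the highest other group were among them. ANXA1 read 7.37 TPM in that library, against 0.276 and 0.173 TPM in the others of its group.

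BIRC2, BIRC3 and TMEM123, neighbours on chromosome 11 (102317450 to 102470384), stood at 0.032, 0.0711 and 0.226 TPM in BJAB, against means of 31.5, 69 and 159 TPM in the other groups. The hypothesis of a lost stretch was tested by shuffling the 253 silent genes among 9646, and a share of 0.145 of the 10000 shuffles held a run as long. Silent genes also lay side by side elsewhere, in a run of 3 on chromosome 10 and in a pair of runs of 4 on chromosome X. A run anywhere among the 9646 genes counted, so the test asks only whether silent genes adjoin more than when shuffled. The test did not back the hypothesis and does not decide it, and a loss cannot be told apart from separate silencing here.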
